A study of Mus musculus with 40 samples.

How the data were processed

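RNA sequencing libraries had been made from sorted bone marrow cells of mice 6 to 8 weeks old. Per the labels, both stages were sorted by surface CD19 and B220 in the absence of IgM; pro-B cells were in addition positive for c-Kit and negative for CD25, and pre-B cells the reverse. The libraries were strand-specific poly(A) libraries read as single reads of 65 bases. The deposited files are 4 tables, and the values of the 2 tables used here are raw read counts per Ensembl gene, with no normalization by the authors. The submitters' processing notes name TopHat2 (versions 2.0.6 and 2.1.0) and HTSeq without saying which table used which, and the strand setting of the counting is not given. The genome build is not stated. The coordinates in the tables were checked against the GENCODE annotation of GRCm38, and 99.9% of the gene identifiers found in both overlapped at the same place.

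The columns of the table of experiment 2 (9 libraries) and of experiment 3 (9 libraries) carry group names and replicate numbers, and 18 columns were used. In experiment 2 the column names taken as Ter5/wt;Rag1ko give the knockout but no matching allele name. They were assigned because only that label joins Rag1ko to a second allele. In experiment 3 the column name of 1 group matches no label, and it was taken as Ter5H∆TM because it was the only group left. The 16 columns of the table of experiment 1 and the 6 columns of the table of experiment 4 could not be matched to samples from their names and were not analysed here. For that reason 5 of the 10 planned comparisons were made, and the planned differences between experiments 1 and 3, 3 and 4, and 2 and 4 were not run. Each group had 3 libraries. The labels do not state that replicates come from separate mice or that replicate numbers pair the groups. The Rag1ko libraries of experiment 3 serve as the reference of both allele groups, and the comparison of these allele groups uses the same libraries again, so the 3 comparisons of experiment 3 are not independent. No library was a copy of another one of its group (0 identical pairs).

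Library totals were between 9618817 and 17398804 counts in experiment 2 and between 14007489 and 20817106 in experiment 3. CPM values, counts scaled to a common library total, were computed with library sizes scaled by TMM, and log2 CPM with a prior count of 2. The summed CPM of V genes used library totals without TMM. A count of 0 in a group of 3 libraries leaves room for 3 counts, which covers counting error only. Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 after its default filter on low counts, with 1 fit per experiment and a group factor only. This tested 12383 of 21167 genes in experiment 2 and 12662 of 20905 in experiment 3. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a comparison, with a threshold of 0.05. All p-values are two-sided. The SE of a log2 fold change was back-calculated from the test, as the absolute log2 fold change divided by the square root of F.

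A set of 27 gene lists was fixed before the data were examined, as were the comparisons, the tests and the alternatives unless stated otherwise. The lists cover developmental stages, signalling and transcription factors, cell cycle and metabolism, stress and interferon responses, and markers of other cell types that a sort could hold. Each list was tested with camera (limma 3.58.1) against all other genes with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. The p-values of 26 lists per comparison were adjusted together, since the list of light chain constant genes had too few tested members. Of the 43 list calls made with the preset correlation, 42 were lost with the estimated one, and the pro-B stage list between WT pre-B and Rag1ko pro-B cells held. The names of the genes in the text follow a rule with 3 parts. It takes Rag1, Rag2, Ighm, Igkc, Kit and Il2ra, whatever their result. It takes per comparison the 8 genes with the largest higher and the 8 with the largest lower log2 fold change among those past the threshold, with a mean of at least 5 CPM and every library of one group beyond every library of the other (10% of genes would separate so by chance), leaving out immunoglobulin and unnamed genes. It takes at most 4 members of a list as examples by smallest p. Ighv1-85, Gm3608, Gm12666 and S100a8 were chosen after their values were seen.

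The pre-B signature took, by smallest p and without immunoglobulin genes, at most 200 genes per direction with an adjusted p under 0.05 and a log2 fold change of at least 1 between WT pre-B and Rag1ko pro-B cells, and in experiment 3 it used the 194 higher and 200 lower genes that passed the filter on low counts there. The signature had been planned from experiment 1, and the use of experiment 2 was chosen after seeing which columns could be matched. Differences of scores were tested with a two-sided exact permutation test.

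The calls were tested on simulated data in which 100 genes of each size were changed. The changed genes were drawn from those above a minimum mean CPM, so changes of genes with few reads were not covered. edgeR called between 70% and 90% of genes changed 2-fold and between 95% and 99% of genes changed 4-fold in the 5 comparisons, and at most 0.117% of unchanged genes. The list test found a raised list in each of the 5 comparisons and called 0 of 26 unchanged lists. The simulated genes were drawn independently of each other, so these results do not cover genes or lists whose members vary together.

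The alternatives were DESeq2 1.42.0, RLE scaling, library totals only, other filters on low counts, no immunoglobulin genes, a fit of the 2 groups alone, a replicate block, a threshold of 2-fold, and leaving out each library in turn. A covariate for myeloid markers, a signature without interferon genes and a joint fit of experiments 2 and 3 for the difference between their changes from Rag1ko cells were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.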

Results

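Pro-B and pre-B cells are consecutive stages of B cell development in the bone marrow. Pro-B cells rearrange the immunoglobulin heavy chain locus (Igh), and cells that make a heavy chain go on to the pre-B stage, where the light chain loci rearrange. A knockout of Rag1, which encodes a subunit of the V(D)J recombinase, stops this rearrangement. The labels name mice with Igh alleles called Ter5, Ter5H and Ter5H∆TM, without giving their sequences. The comparisons address how the transcriptome of pro-B cells with these alleles differs from that of Rag1ko pro-B cells, and how far it lies toward that of pre-B cells. The groups, of 3 libraries each, were WT pre-B, Rag1ko pro-B and Ter5/wt;Rag1ko pro-B cells in experiment 2, and Rag1ko, Ter5H and Ter5H∆TM pro-B cells in experiment 3. The labels do not say that the replicates come from separate mice, so the p-values measure the spread between samples only.

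WT pre-B cells differed from Rag1ko pro-B cells in the genes that define the stages. Il2ra, which encodes the CD25 chain used as the pre-B sort marker, was read at 498 ± 30.7 CPM (read counts scaled to a common library total; SD, n = 3) in pre-B cells and 0.977 ± 0.248 in Rag1ko pro-B cells. Kit, the pro-B sort marker, was at 1.31 ± 0.0931 against 118 ± 16.4 CPM. Dntt, which encodes the terminal transferase that adds nucleotides at V(D)J joints, had a log2 fold change of -10.55 ± 0.25 (SE), and Polm, a polymerase of end joining, one of 8.62 ± 0.17. The heavy chain constant gene Ighm (log2 fold change 1.81 ± 0.15) and the kappa light chain constant gene Igkc (5.80 ± 0.29) were both higher in pre-B cells.

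Of the 17 genes of the pro-B stage list, 15 were lower and 1 was higher in WT pre-B than in Rag1ko pro-B cells, with the same counts when adjusted over the list alone. The higher one was Nrgn (4.51), and the lower ones included the surrogate light chain genes Igll1 (-7.15) and Vpreb1 (-7.04; log2 fold changes here and below). The list test gave an adjusted p of 4.65e-07, and an adjusted p of 0.0472 with an estimated correlation. Of the 22 genes of the pre-B stage list, 16 were higher and 2 lower, as they were when adjusted over the list alone (adjusted p = 2.75e-07, and adjusted p = 0.231 with an estimated correlation). Ikzf3, a transcription factor of the Ikaros family, was higher by 8.39, and Cd22, an inhibitory receptor of B cells, by 3.99. Cd2 was at 182 ± 22.8 CPM in pre-B cells, against 1 read in all 3 Rag1ko libraries. In the list of pre-B cell receptor (pre-BCR) signalling components 11 of 20 genes were higher and 5 lower (12 and 5 adjusted over the list alone; 7 and 4 without Rag1ko replicate 3), among them the kinases Blk (4.28), Syk (2.20), Lyn (2.11) and Fyn (-1.92). The list as a whole did not pass its test (adjusted p = 0.0868). In the S phase and replication list 16 of 20 genes were lower and none was higher (the same counts adjusted over the list alone), with Tyms at -1.99 and Mcm6 at -1.36. The adjusted p of that list was 0.00113, and the adjusted p with an estimated correlation was 0.538. edgeR found 0 higher genes in it, also at an unadjusted p under 0.05, and DESeq2 found 0.

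Across the genome, 3159 genes were higher and 3740 lower in WT pre-B than in Rag1ko pro-B cells, of 12383 tested (edgeR, adjusted p under 0.05). With library totals as the only scaling the split was 2339 higher and 4390 lower, since that scaling moved the median log2 fold change by -0.14. At least 2-fold changes made up 1199 and 2217 of these genes. Stage and genotype differed together in this comparison, because experiment 2 has no WT pro-B group. In 1 of the 3 pre-B libraries, replicate 1, the 10 most read genes took 12.3% of the counts, against 5.47% and 5.68% in the other two. The labels of that library disagree, since its title says pre-B and its cell type field lists the pro-B sort markers. Its counts had the pre-B pattern for Kit and Il2ra, as the plot of single genes shows.

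**Figure D1:**
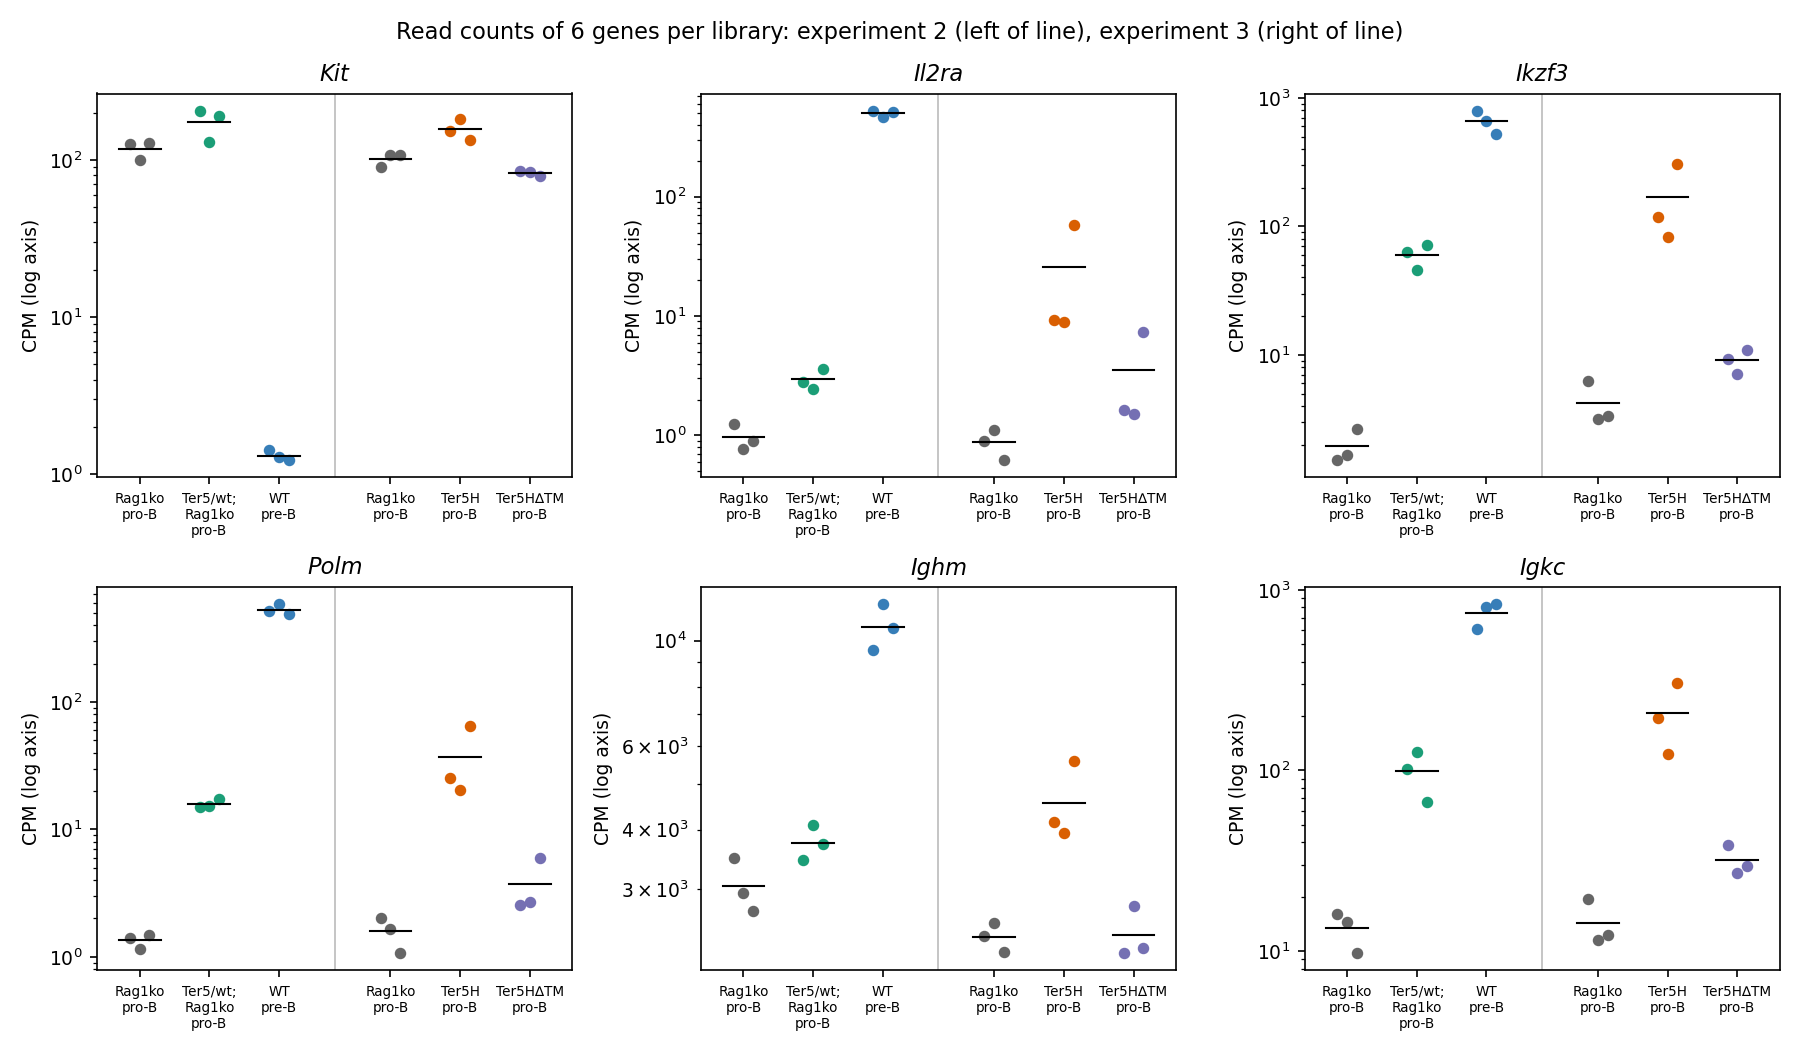
CPM (log axis) of Kit, Il2ra, Ikzf3, Polm, Ighm and Igkc in the 18 libraries, 1 point per library, with a bar at the mean of each group of 3; experiment 2 is left of the grey line and experiment 3 right of it. Igkc had a mean of 98.8 CPM in Ter5/wt;Rag1ko and 208 CPM in Ter5H pro-B cells, against 13.4 and 14.4 CPM in the Rag1ko pro-B cells of the same experiment.

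Ter5/wt;Rag1ko pro-B cells, which per the labels carry 1 Ter5 allele and a Rag1 knockout, had higher levels of several pre-B genes than Rag1ko pro-B cells. Ikzf3 was at 60.3 ± 13.6 against 1.95 ± 0.608 CPM (SD, n = 3; log2 fold change 4.94 ± 0.27, SE), Polm at 15.8 ± 1.20 against 1.35 ± 0.168 CPM (3.55 ± 0.16), and Cd22 at 83.2 ± 9.14 against 14.1 ± 1.54 CPM (2.56 ± 0.14). Igkc was higher by 2.88 ± 0.25, at 98.8 ± 30.3 CPM. The sort marker Il2ra was higher by 1.60 ± 0.22 but reached only 2.95 ± 0.571 CPM, and Kit did not pass the test (0.57 ± 0.16, adjusted p = 0.105). Ighm did not pass it either (0.30 ± 0.15, adjusted p = 0.488).

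Among the genes with a mean of at least 5 CPM and no overlap between the groups, immunoglobulin and T cell receptor genes and unnamed gene models left out, those with the largest higher values beside these were Crhbp (2.93), the proton channel gene Hvcn1 (2.83), the Fc receptor-like gene Fcrla (2.75), Cd74 (2.33) and F5 (2.16). The call of Cd74 was lost without Rag1ko replicate 2 (2.30) or Ter5/wt;Rag1ko replicate 1 (2.52), 2 (1.93) or 3 (2.46), and its value was 3.15 without Rag1ko replicate 3. Under the same conditions the genes with the lowest values were Dlg2 (-2.78), Ccm2l (-2.67), Sgsm1 (-2.47), Dnajc6 (-2.38), Eya2 (-2.36), Gria2 (-2.35), Ccdc33 (-2.19) and Zan (-2.16), with Ccm2l at -3.26 without Ter5/wt;Rag1ko replicate 2. Gria2 lost its call without Ter5/wt;Rag1ko replicate 2 (-2.18) or 3 (-2.13) and was at -1.74 without Rag1ko replicate 1. In the pre-B stage list 8 of 22 genes were higher and 1 was lower (11 and 3 adjusted over the list alone), with Irf4, a transcription factor of light chain rearrangement, at 1.40 and the homing receptor gene Sell at 1.34. Between WT pre-B and Rag1ko pro-B cells Sell did not pass the test (0.35, adjusted p = 0.0798). Without Rag1ko replicate 2 or 3 or Ter5/wt;Rag1ko replicate 3, 5 genes were higher. The list test gave an adjusted p of 3.71e-09, and an adjusted p of 0.266 with an estimated correlation. In the pro-B stage list 2 of 17 genes were higher and 2 lower (3 and 3 adjusted over the list alone), with Nrgn at 3.49, Socs2 at 1.14, Dntt at -0.76 and Flt3 at -1.51, and the list as a whole did not pass (adjusted p = 0.992). The calls of both lower genes were lost without Rag1ko replicate 2 or Ter5/wt;Rag1ko replicate 1 or 3, that of Dntt also without Rag1ko replicate 1 (between -0.72 and -0.67 in these 4), and that of Flt3 also without Rag1ko replicate 3 or Ter5/wt;Rag1ko replicate 2 (between -1.71 and -1.13 in these 5). Among the pre-BCR signalling components Blk was higher (1.72) and 2 of the 20 genes were lower, Bank1 at -1.28 and Fyn at -0.41. Adjusted over the list alone, 3 were higher and 2 lower, and the list did not pass (adjusted p = 0.785). The call of Fyn was lost without any 1 of the 6 libraries, with log2 fold changes between -0.44 and -0.39 over all alternatives. Markers of other cell types moved as well: edgeR called none of the 6 tested erythroid markers (5 lower adjusted over the list alone, 5 lower and 0 higher at an unadjusted p under 0.05, 2 lower by DESeq2), with a median of -1.12 and an adjusted p of 0.00021 for the list (0.358 as an adjusted p with an estimated correlation). Of 7 markers of T and NK cells 2 were lower (3 adjusted over the list alone), with an adjusted p of 0.0411 for the list, and an adjusted p of 0.358 with an estimated correlation. Both, Klrb1c (-2.15) and Cd4 (-2.72), lost their calls without Ter5/wt;Rag1ko replicate 1 (-2.14 and -2.29) or 3 (-1.86 and -2.84), and Cd4 also without Rag1ko replicate 2 (-2.55) or 3 (-2.73). Of 8 plasma cell markers 2 were higher and 1 was lower (4 and 1 adjusted over the list alone; adjusted p = 0.00291), and of 10 markers of immature and mature B cells 2 were higher and 1 was lower (3 and 1 adjusted over the list alone; adjusted p = 0.0411). Of 7 early progenitor markers 1 was lower (2 adjusted over the list alone; adjusted p = 0.0411). Each of these 3 lists had an adjusted p of 0.266 with an estimated correlation. Of their called genes, the plasma cell marker Mzb1 (-0.72) lost its call without Rag1ko replicate 1 or 2 or Ter5/wt;Rag1ko replicate 1 or 3 (between -0.69 and -0.61), and the B cell markers Ccr7 (0.76) and Cd69 (-0.71) without any 1 library except Rag1ko replicate 3 (between 0.61 and 0.84, and between -0.80 and -0.57). The called progenitor marker was Flt3.

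In all, 159 genes were higher and 204 lower in Ter5/wt;Rag1ko than in Rag1ko pro-B cells. The count of 363 was 156 without Rag1ko replicate 2, 184 without Ter5/wt;Rag1ko replicate 1 and 157 without its replicate 3. It was 549 with DESeq2 and also with a replicate block, 701 without a filter on low counts, and 218 at a change of at least 2-fold.

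Ter5H pro-B cells, from mice with Ter5H on both Igh alleles and no Rag1 label, also had higher levels of several pre-B genes and of immunoglobulin constant gene transcripts than Rag1ko pro-B cells. Ikzf3 was at 168 ± 118 against 4.24 ± 1.74 CPM (SD, n = 3; log2 fold change 5.30 ± 0.53, SE) and Polm at 36.9 ± 24.4 against 1.58 ± 0.481 CPM (4.53 ± 0.54). Both were highest in Ter5H replicate 3, and without it the log2 fold changes were 4.55 and 3.82. Ighm was higher by 0.94 ± 0.15 and Igkc by 3.85 ± 0.35. Kit was higher by 0.62 ± 0.12. Ly6a, which encodes the surface protein Sca-1, and Iigp1, which encodes an interferon-inducible GTPase, were lower, with Ly6a at 5.06 ± 1.53 against 119.6 ± 32.8 CPM and Iigp1 at 19.7 ± 5.86 against 184 ± 52.2 CPM.

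Il2ra was at 25.5 ± 28.4 against 0.877 ± 0.238 CPM, a log2 fold change of 4.84 ± 0.96, and its call was lost without Rag1ko replicate 2 (5.04) or replicate 3 (4.63). Ter5H replicate 3 had 58.3 CPM, against 9.32 and 8.86 CPM in the other two, and without it the log2 fold change was 3.34. Among the genes with a mean of at least 5 CPM and no overlap between the groups, immunoglobulin and T cell receptor genes and unnamed gene models left out, Il9r was the highest (5.83; 3.38 without Ter5H replicate 3), and it lost its call without Rag1ko replicate 1 (5.60036), 2 (6.12) or 3 (5.76). It was followed by genes that included Col5a3 (5.81), the insulin receptor substrate gene Irs1 (4.56), Fcrla (4.47) and Faim3 (4.21), which were at 4.49, 4.54, 3.83 and 3.20 without Ter5H replicate 3. The lowest under these conditions were Tgtp1 (-5.25), Ly6a (-4.55), Sgsm1 (-3.57), Iigp1 (-3.22), Ccm2l (-2.98), Klk8 (-2.85), Rnase12 (-2.79) and Eya2 (-2.76). In the pre-B stage list 10 of 22 genes were higher and 1 was lower (16 and 2 adjusted over the list alone), among them Irf4 (1.93), Bach2 (1.67) and Cd22 (2.95). The 10 were 7 without Rag1ko replicate 2 or 3. The adjusted p of that list was 3.32e-08, and the adjusted p with an estimated correlation was 0.773. In the list of B lineage transcription factors 5 of 24 genes were higher (9 adjusted over the list alone), with Pax5 at 0.62, and the adjusted p was 1.50e-05 (0.773, again as an adjusted p with an estimated correlation). In the NF-kB target list 5 of 15 genes were higher and 1 was lower (8 and 1 adjusted over the list alone), with Nfkb2 at 1.48, Relb at 1.60 and Cd40 at 2.83 (2.02 without Ter5H replicate 3). Without Rag1ko replicate 3, 3 were higher, and the lower gene lost its call without Rag1ko replicate 1 or 3 or Ter5H replicate 1 or 2. The adjusted p was 0.0048, and the adjusted p with an estimated correlation was 0.773. Of the pre-BCR signalling components 8 of 20 were higher and 1 was lower (9 and 2 adjusted over the list alone), with Lyn at 0.98, and the list did not pass its test (adjusted p = 0.0546). The 8 higher genes were 3 without Rag1ko replicate 2 or Ter5H replicate 3, 1 without Rag1ko replicate 3, and 4 and 5 without Ter5H replicates 1 and 2. In the pro-B stage list 3 of 17 genes were higher and 3 lower (3 and 5 adjusted over the list alone), with Nrgn at 3.06, Flt3 at -2.45 and Dntt at -1.29 (adjusted p of the list 0.362). Socs2 (0.77) lost its call without any 1 of the 6 libraries (between 0.63 and 0.86), and the 3 lower genes were 2 without Rag1ko replicate 2 or Ter5H replicate 1.

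Of the 19 genes of the interferon response list, 13 were lower and none was higher in Ter5H than in Rag1ko pro-B cells (16 lower adjusted over the list alone; 7 without Rag1ko replicate 2). The median log2 fold change was -0.79, with the transcription factor genes Irf7 at -1.57 and Stat1 at -0.67, and Usp18 at -1.31. The adjusted p was 6.44e-11, and the adjusted p with an estimated correlation was 0.41. edgeR found 0 higher genes of this list also at an unadjusted p under 0.05, and DESeq2 found 0 higher and 15 lower. In the MHC class II list 4 of 10 genes were lower (1 higher and 6 lower adjusted over the list alone), with H2-Ab1 at -1.10, the only one still called without Rag1ko replicate 2 or 3 or Ter5H replicate 1. H2-Aa (-1.90) lost its call in these 3 fits and without Ter5H replicate 3 (between -1.98 and -1.46), H2-DMa (-1.12) in these 3 and without Ter5H replicate 2 (between -1.06 and -0.95), and Ciita (-1.50) in these 3 and without Ter5H replicate 2 or 3 (between -1.67 and -0.87, the latter without Rag1ko replicate 3). The adjusted p of the list was 0.0048, and the adjusted p with an estimated correlation was 0.773. In Ter5/wt;Rag1ko against Rag1ko cells 1 gene of the list, Cd74, was higher (3 higher adjusted over the list alone, 4 without Rag1ko replicate 3, and 0 without Rag1ko replicate 2 or any 1 Ter5/wt;Rag1ko library; median 0.63, adjusted p = 0.000725, and adjusted p = 0.36 with an estimated correlation). Of 9 markers of T and NK cells 2 were lower and 1 higher (3 and 1 adjusted over the list alone), with Thy1 at -1.88, and the list did not pass its test (adjusted p = 0.11). Klrb1c (-0.93), the other lower gene, lost its call without Rag1ko replicate 2 or 3 or Ter5H replicate 1 or 3 (between -0.89 and -0.84), and Zap70 (0.89), the higher one, without Rag1ko replicate 2 or 3 or Ter5H replicate 1 or 2 (between 0.69 and 0.85). Myeloid transcripts varied widely within each group of experiment 3. S100a8, a neutrophil gene, was at 39.2, 661 and 587 CPM in the 3 Rag1ko libraries, at 45.4, 262 and 389 CPM in the Ter5H ones and at 94.8, 236 and 636 CPM in the Ter5H∆TM ones. It was lowest in replicate 1 of each group. Deviations of log2 CPM from the group mean correlated between the libraries numbered 1 of different groups (r between 0.55 and 0.65). The r was between 0.39 and 0.64 for those numbered 3, and between -0.05 and 0.09 for those numbered 2. The labels do not state a pairing, and the main fits had no replicate block.

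In all, 723 genes were higher and 694 lower in Ter5H than in Rag1ko pro-B cells, of 12662 tested. The count of 1417 was 771 without Rag1ko replicate 2, 891 without Rag1ko replicate 3, 823 without Ter5H replicate 1, 932 without Ter5H replicate 3, 911 from the 2 groups alone and 602 at a change of at least 2-fold.

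Fewer genes differed between Ter5H∆TM and Rag1ko pro-B cells, and heavy chain V genes were among them. Of the 29 heavy chain V genes tested, 17 were higher and 2 lower (14 and 7 in Ter5H, and 8 and 12 of 90 in Ter5/wt;Rag1ko, against Rag1ko cells). Together the Ighv genes were at 166 ± 29.6 CPM (SD, n = 3) against 35.0 ± 12.8 in Rag1ko cells, with library totals as the only scaling. On the same scale they were at 44.1 ± 3.16 CPM in Ter5H cells. In experiment 2 they were at 38.3 ± 7.41 CPM in Ter5/wt;Rag1ko and 42.6 ± 3.79 CPM in Rag1ko cells. All these values have the limit that reads of similar V genes can be counted for each other. Fnbp1l was at 40.2 ± 4.54 CPM in Ter5H∆TM against 5.71 ± 1.53 CPM in Rag1ko cells (log2 fold change 2.81 ± 0.22, SE). Iigp1 was at 19.2 ± 8.80 against 184 ± 52.2 CPM (-3.26 ± 0.37), and Ly6a at 19.7 ± 6.80 against 119.6 ± 32.8 CPM (-2.60 ± 0.31). Igkc (1.14 ± 0.33, adjusted p = 0.32), Il2ra (1.98 ± 0.94, adjusted p = 0.834), Kit (-0.31 ± 0.12, adjusted p = 0.697) and Ighm (0.02 ± 0.14, adjusted p = 0.988) did not pass the test.

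With a mean of at least 5 CPM and no overlap between the groups, immunoglobulin and T cell receptor genes and unnamed gene models left out, the genes with the lowest values were Tgtp1 (-3.71), Iigp1, Serpina3f (-3.10), Ly6a, Gbp6 (-2.31), Igtp (-1.97), Tgtp2 (-1.89) and Gbp2 (-1.59), of which Tgtp1, Tgtp2, Iigp1, Igtp, Gbp2 and Gbp6 encode interferon-inducible GTPases, which were not tested as a group. Tgtp1 and Tgtp2 are close paralogs, so a read of one can be counted for the other. Beside Fnbp1l, 6 other genes outside the immunoglobulin loci were higher, such as Pla2g12a (0.76) and Capza1 (0.65), and both of these calls were lost without Ter5H∆TM replicate 2 (0.73 and 0.59). Reln (2.29) lost its call without any 1 of the 6 libraries except Rag1ko replicate 1 (between 2.11 and 2.43), Zfp386 (0.80) without Rag1ko replicate 1 or 3 or Ter5H∆TM replicate 1 or 3 (between 0.71 and 0.77), and Gclm (0.57) without any 1 of the 6 (between 0.54 and 0.62). In the interferon response list 2 of 19 genes were lower (14 adjusted over the list alone), Stat1 (-0.82) and Zbp1 (-0.71), with a median of -0.60. Zbp1 lost its call without any 1 of the 6 libraries except Rag1ko replicate 1, with log2 fold changes between -0.78 and -0.62 over all alternatives. The list test gave an adjusted p of 2.04e-18, and an adjusted p of 0.127 with an estimated correlation. In the MHC class II list 2 of 10 genes were lower (6 adjusted over the list alone; adjusted p = 4.20e-07, and adjusted p = 0.513 with an estimated correlation). These were Ciita (-2.65), lost without any 1 Ter5H∆TM library (between -2.95 and -2.002 over all alternatives, the latter without Rag1ko replicate 3), and H2-Ab1 (-0.82), lost without Rag1ko replicate 2 or 3 or Ter5H∆TM replicate 1 or 3 (between -0.98 and -0.72). No gene of the pre-B stage list was called by edgeR (1 adjusted over the list alone, 3 higher at an unadjusted p under 0.05, and 1 by DESeq2), with Irf4 at 0.46 ± 0.10 (adjusted p = 0.128). The list as a whole was higher (median 0.32, adjusted p = 0.00185, and adjusted p = 0.955 with an estimated correlation). So was the list of pre-BCR signalling components (median 0.11, adjusted p = 0.00216, and adjusted p = 0.955 with an estimated correlation), of which edgeR called 0 genes (0 adjusted over the list alone, 1 higher at an unadjusted p under 0.05, and 0 by DESeq2).

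In all, 25 genes were higher and 54 lower, of which 7 and 52 lay outside the immunoglobulin genes. The count of 79 was 51 without Rag1ko replicate 2, 50 without Rag1ko replicate 3, 51, 45 and 49 without Ter5H∆TM replicates 1, 2 and 3, 51 without the immunoglobulin genes, 119 with a myeloid covariate and 200 with DESeq2.

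Ter5H∆TM pro-B cells had lower levels of several pre-B genes and of immunoglobulin constant gene transcripts than Ter5H pro-B cells. Ikzf3 was at 9.14 ± 1.98 CPM in Ter5H∆TM and 168 ± 118 CPM in Ter5H cells (SD, n = 3; log2 fold change -4.21 ± 0.50, SE), and Irs1 at 0.947 ± 0.115 and 14.3 ± 1.71 CPM (-3.91 ± 0.26). Ighm (-0.92 ± 0.15), Igkc (-2.72 ± 0.33) and Kit (-0.92 ± 0.12) were lower in Ter5H∆TM cells. Il2ra did not pass the test (-2.87 ± 0.84, adjusted p = 0.0972). Polm (-3.30), Fcrla (-2.96), Whrn (-2.92) and Srgap3 (-2.46) were lower in Ter5H∆TM cells (without Ter5H replicate 3, Ikzf3 was at -3.45, Polm at -2.59, Fcrla at -2.33 and Whrn at -2.26), and Sgsm1 (3.78), Ccm2l (3.49), Zan (2.99), Dlg2 (2.62) and Myl10 (2.54) were higher. Of the other genes the naming rule takes, Faim3 (-3.03) lost its call without any 1 Ter5H∆TM library (between -3.14 and -2.82) and was at -2.02 without Ter5H replicate 3. Col5a3 (-2.99) lost it without any 1 of the 6 libraries except Ter5H replicate 2 (between -3.22 and -1.68, the latter without Ter5H replicate 3), and Pgr (2.97) without Ter5H replicate 1 (3.09) or 3 (2.67) or Ter5H∆TM replicate 3 (2.87). Ptpn14 (2.77) lost it without any 1 library except Ter5H∆TM replicate 3 (between 1.90 and 3.02, the former without Ter5H∆TM replicate 1), and Gria2 (2.60) without any 1 except Ter5H∆TM replicate 2 (between 1.77 and 2.81, the former without Ter5H∆TM replicate 3).

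In the pre-B stage list 6 of 22 genes were lower and 1 was higher in Ter5H∆TM than in Ter5H cells (10 and 2 adjusted over the list alone; the higher call was lost without Ter5H replicate 1 or 2 or Ter5H∆TM replicate 2 or 3), with Irf4 at -1.48, Bach2 at -1.38 and Cd22 at -2.33. The adjusted p was 1.77e-07, and the adjusted p with an estimated correlation was 0.702. In the list of B lineage transcription factors 6 of 24 genes were lower (8 adjusted over the list alone; 4 without Ter5H replicate 2 or any 1 Ter5H∆TM library), with Pax5 at -0.59 (adjusted p = 1.77e-07, and adjusted p = 0.702 with an estimated correlation). In the pro-B stage list 2 of 17 genes were higher, Flt3 (2.18) and Dntt (1.08), and 2 were lower (5 and 3 adjusted over the list alone; adjusted p of the list 0.348). In the interferon response list 1 of 19 genes was higher, Irf7 at 0.89 (lost without Ter5H replicate 1 or any 1 Ter5H∆TM library, between 0.83 and 0.99), also when adjusted over the list alone (median 0.18, adjusted p = 0.0334, and adjusted p = 0.702 with an estimated correlation). In all, 368 genes were higher and 232 lower. The count of 600 was 320 without Ter5H replicate 1, 397 without Ter5H replicate 2, 343, 284 and 291 without Ter5H∆TM replicates 1, 2 and 3, 304 at a change of at least 2-fold and 1007 with DESeq2.

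**Figure D2:**
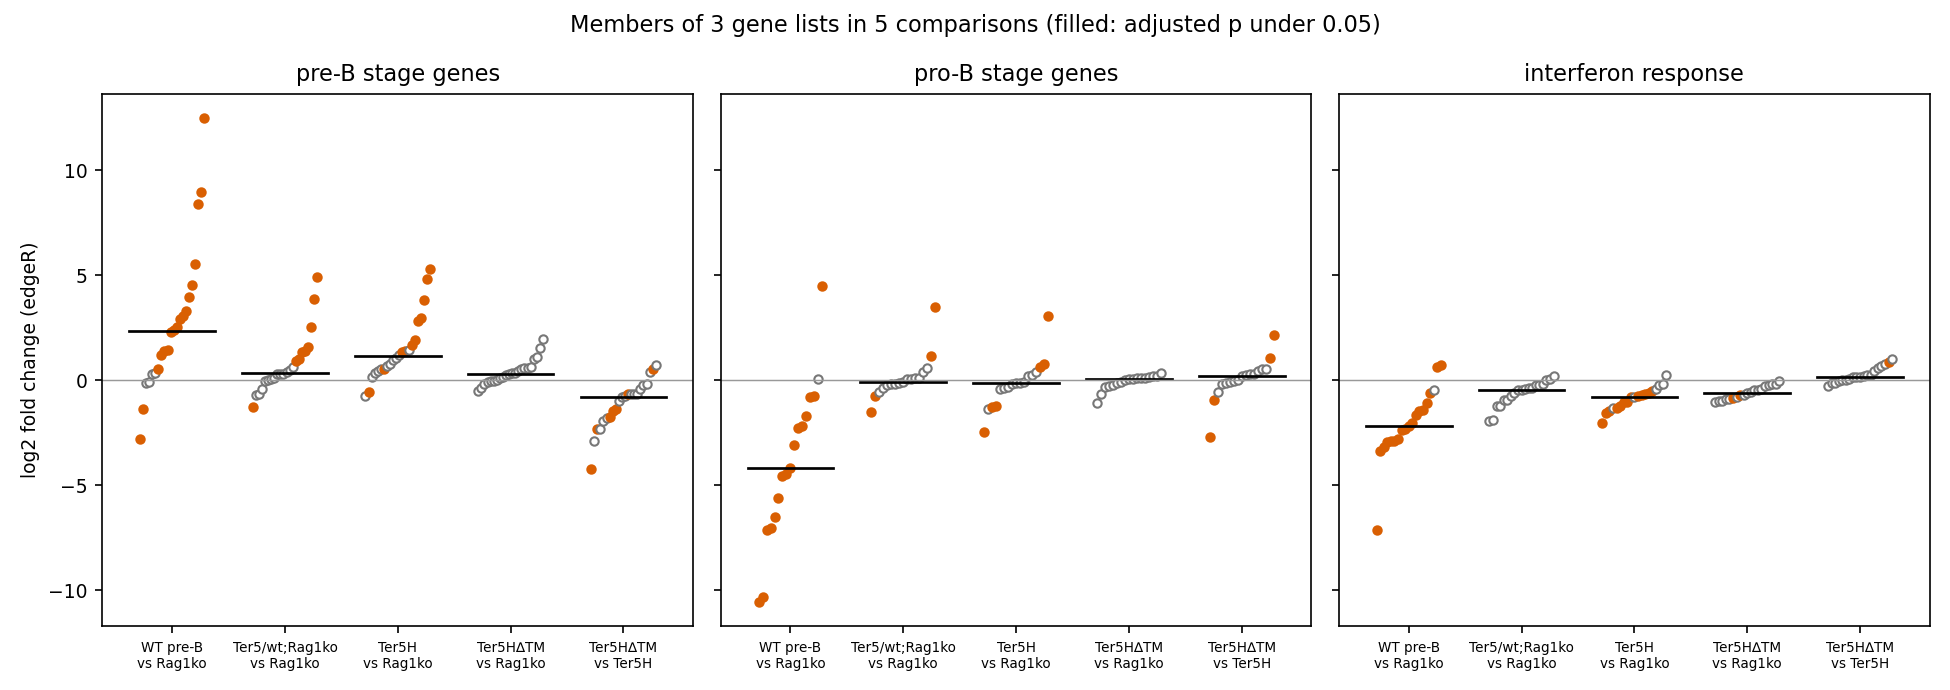
Log2 fold changes (edgeR) of the members of the pre-B stage, pro-B stage and interferon response lists in the 5 comparisons, 1 point per gene ordered by value, filled where the adjusted p was under 0.05, with a bar at the median. The median of the interferon list was -0.79 in Ter5H and -0.60 in Ter5H∆TM against Rag1ko pro-B cells, and 0.18 between Ter5H∆TM and Ter5H; the highest point of the pre-B list is Cd2, drawn at its fitted value although it had 1 read in the Rag1ko libraries.

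Rag1 transcripts were counted over the whole gene, and the labels do not say which part the knockout alters, so these counts do not check the labels. Rag1 did not pass the test in any of the 5 comparisons, at 3558 ± 591 CPM in WT pre-B, 2598 ± 708 CPM in Rag1ko and 2373 ± 577 CPM in Ter5/wt;Rag1ko cells of experiment 2. In experiment 3 it was at 1652 ± 409.8 CPM in Rag1ko, 1658 ± 404 CPM in Ter5H and 1378 ± 280.0 CPM in Ter5H∆TM cells. Rag2 was lower in WT pre-B than in Rag1ko pro-B cells (-0.92 ± 0.18, SE) and did not pass the test in the other 4 comparisons. In GRCm38 coordinates Rag1 lies on chromosome 2 from 101638282 to 101649501, Il2ra on chromosome 2 from 11642792 to 11693191, Kit on chromosome 5 from 75574916 to 75656722, Igkc on chromosome 6 from 70726435 to 70726757 and Ighm on chromosome 12 from 113418950 to 113422730.

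A pre-B signature placed the groups on a scale from Rag1ko pro-B to WT pre-B cells, along which stage and genotype differ together. The signature held the 200 higher and the 200 lower genes with the smallest p among those outside the immunoglobulin genes that changed at least 2-fold between WT pre-B and Rag1ko pro-B cells of experiment 2. A library's score was the difference of their mean log2 CPM. Genes that differ only with the Rag1 label could thus raise the score of Ter5H and Ter5H∆TM cells, whose labels name no Rag1 knockout. The score was -2.41 ± 0.06 in Rag1ko pro-B, -1.31 ± 0.15 in Ter5/wt;Rag1ko pro-B and 5.68 ± 0.09 in WT pre-B cells (SD, n = 3). In experiment 3 it was -2.05 ± 0.07 in Rag1ko, -0.29 ± 0.52 in Ter5H and -1.76 ± 0.09 in Ter5H∆TM pro-B cells. The score of Ter5/wt;Rag1ko cells was higher than that of Rag1ko cells by 1.10 (SE 0.09), 13.6% of the distance to WT pre-B cells. That distance is one of mean log2 CPM and does not give a share of cells. Pre-B cells inside the sorted gate would raise the score as well. As the Rag1ko libraries of experiment 2 also define the signature, 50 simulated groups without a change gave a difference of 0.04 on average and 0.10 at most. Their genes were drawn independently of each other, so 0.10 does not cover variation that the genes of a library share. In experiment 3 the difference from Rag1ko cells was 1.76 (SE 0.30) for Ter5H and 0.29 (SE 0.06) for Ter5H∆TM (0.45 with 50 signature genes per direction), and Ter5H∆TM lay below Ter5H by -1.47 (SE 0.31). Ter5H replicate 3 stood apart, at 0.31 against -0.55 and -0.63, and without it the Ter5H difference was 1.46. In each of the 4 differences every library of one group lay beyond every library of the other, which gives p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 allows.

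**Figure D3:**
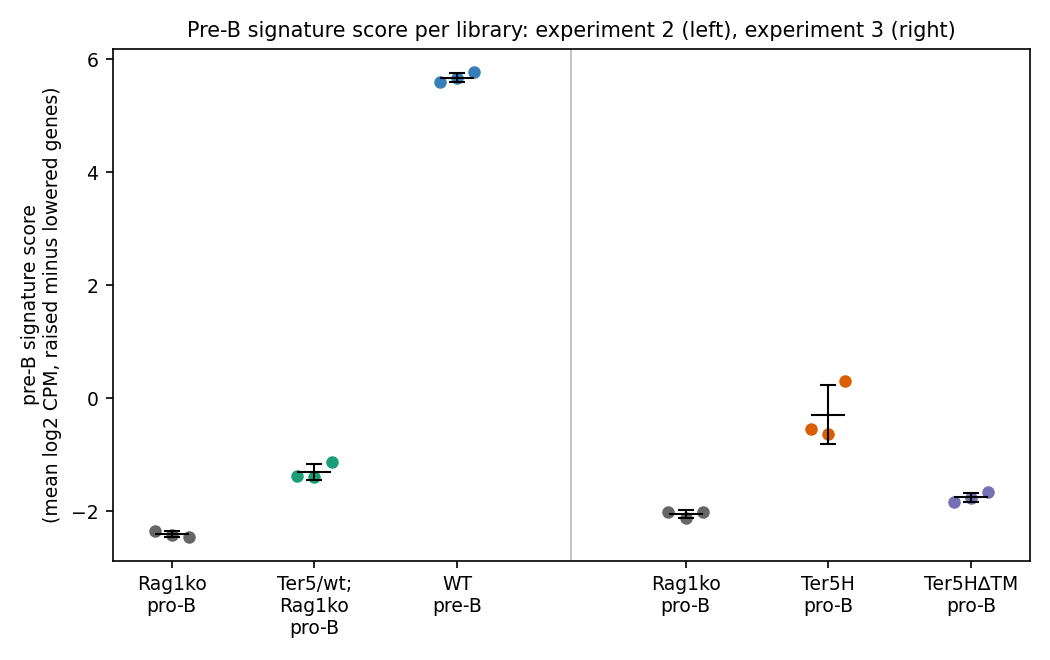
Pre-B signature score of each of the 18 libraries (difference of mean log2 CPM between the raised and the lowered signature genes), 1 point per library, with a bar at the mean of each group of 3; experiment 2 is at the left and experiment 3 at the right. The WT pre-B libraries lie near 5.68, the Ter5/wt;Rag1ko libraries near -1.31 and the Rag1ko libraries near -2.41 (experiment 2) and -2.05 (experiment 3).

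The genes of different comparisons were set against each other over the 11997 genes outside the immunoglobulin loci that were tested in both experiments. Of the 676 genes higher in Ter5H than in Rag1ko pro-B cells, 506 were also higher in WT pre-B cells of experiment 2, where 162.6 would be shared if calls were independent, and 59 were lower there. Of the 673 lower ones, 589 were lower there, where 208.8 would be shared, and 13 were higher. The Ter5/wt;Rag1ko and Ter5H comparisons, which share no library, had 112 higher genes (8.28 under independence) and 142 lower genes (10.8) in common. Of the 52 genes lower in Ter5H∆TM than in Rag1ko cells, 43 were also lower in WT pre-B cells (16.1) and 2 were higher there. Ter5H, Ter5H∆TM and WT pre-B cells, whose labels name no Rag1 knockout, were each set against Rag1ko cells. Genes that follow the Rag1 label can therefore add to the overlaps with WT pre-B cells, which the values under independence do not account for. None of the 7 higher and 52 lower genes of Ter5H∆TM was called in Ter5/wt;Rag1ko in either direction by edgeR, where 0.832 would be shared among the lower ones. At an unadjusted p under 0.05, 63 genes were higher and 40 lower in both comparisons and 68 went opposite ways, and with DESeq2 the numbers were 10, 3 and 12.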

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

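The difference tests between experiments 2 and 3, and the tests of myeloid RNA (a covariate), of Rag1 deficiency, of a strain variant, of pre-B cells in the gate and of knocked-in heavy chain reads, were chosen after the results were seen.

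The changes from the Rag1ko cells of the same experiment differed between groups in a joint fit of both tables, in which the Igh allele, its number of copies, the Rag1 label and the experiment differ together. For Ter5/wt;Rag1ko against Ter5H, 12 genes differed, among them Ly6a, by 3.67 on the log2 scale (adjusted p = 0.0281, edgeR), with -0.91 in Ter5/wt;Rag1ko and -4.55 in Ter5H. That count was 5 to 47 when 1 library was left out, with 6 without Rag1ko replicate 2 of experiment 2, 47 without its replicate 3, 5, 6 and 23 without Ter5/wt;Rag1ko replicates 1, 2 and 3, 5 without Rag1ko replicate 2 of experiment 3, and 6 and 7 without Ter5H replicates 1 and 3. For Ter5/wt;Rag1ko against Ter5H∆TM, 116 genes differed, and the count was 57 without Ter5/wt;Rag1ko replicate 1, 60 and 69 without Rag1ko replicates 1 and 2 of experiment 2, 65 without Rag1ko replicate 3 of experiment 3, and 69 and 61 without Ter5H∆TM replicates 2 and 3.

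Among the named genes of that second difference, the change in Ter5/wt;Rag1ko was the higher one for Ikzf3 (3.86, adjusted p = 0.00705), Serpina3f (3.86, adjusted p = 0.0426), Gbp6 (2.59, adjusted p = 0.0326), Hvcn1 (2.43, adjusted p = 0.00166), Crhbp (2.07, adjusted p = 0.0301) and Cd22 (1.96, adjusted p = 0.00432). It was the lower one for Fnbp1l (-4.43, adjusted p = 0.00326), Ccm2l (-3.16, adjusted p = 0.00577), Dlg2 (-2.94, adjusted p = 0.00326), Dnajc6 (-2.89, adjusted p = 0.00499), Sgsm1 (-2.66, adjusted p = 0.00705), Zan (-2.45, adjusted p = 0.0301), Eya2 (-1.93, adjusted p = 0.0111) and Pla2g12a (-1.16, adjusted p = 0.00705). Serpina3f was at 0.76 in Ter5/wt;Rag1ko and -3.10 in Ter5H∆TM, and Fnbp1l at -1.64 and 2.81.

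In the interferon response list 13 of 19 genes were lower in Ter5H and 2 in Ter5H∆TM than in the Rag1ko pro-B cells of experiment 3 (16 and 14 adjusted over the list alone; the 13 were 7 without Rag1ko replicate 2, and the 2 were 1 without any 1 library except Rag1ko replicate 1), and both list calls were lost with an estimated correlation (adjusted p = 0.41 and adjusted p = 0.127). RNA of myeloid cells in the Rag1ko libraries is argued against as the whole cause in Ter5H∆TM. The median of the 19 list genes there was -0.60 with a myeloid covariate (quartiles -0.84 and -0.34). A single Rag1ko library is argued against as well, since the median stayed at or below -0.53 whichever was left out. Both statements cover Ter5H∆TM only. The Rag1 deficiency of the control mice may contribute and cannot be told apart from the Igh alleles in experiment 3, where the labels of the Rag1ko libraries name no Igh allele; between the 2 groups of experiment 2 labelled Rag1ko the median was -0.44 (quartiles -0.93 and -0.23), none of the 19 genes was called (8 lower at an unadjusted p under 0.05, 2 by DESeq2), and the list was called lower with the preset correlation (adjusted p = 0.00021) but, as in experiment 3, not with an estimated one (adjusted p = 0.54). A strain variant carried by the Rag1ko mice cannot be told apart either: 2 genes outside chromosome 2 were read in all libraries labelled Rag1ko and were near absent elsewhere, Gm3608 on chromosome 1 (26.5, 32.2 and 50.5 CPM in the 3 groups labelled Rag1ko, and at most 0.355 CPM in the others) and Gm12666 on chromosome 4 (2.001, 2.40 and 4.78 CPM, and at most 0.0214 CPM). Of the 9 other divisions of the 6 groups, the one between experiments gave 9 such genes and the other 8 gave none.

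In the pre-B stage list 8 of 22 genes were higher and 1 was lower in Ter5/wt;Rag1ko (11 and 3 adjusted over the list alone), and 10 were higher and 1 lower in Ter5H (16 and 2 adjusted over the list alone), against Rag1ko pro-B cells, and both list calls were lost with an estimated correlation (adjusted p = 0.266 and adjusted p = 0.773). The count of 8 was 5 without Rag1ko replicate 2 or 3 or Ter5/wt;Rag1ko replicate 3, and that of 10 was at least 7 whichever library was left out. Pre-B cells inside the sorted gate could contribute, although the gate excludes CD25+ cells. The 16 list genes higher in WT pre-B cells, whatever their result elsewhere, implied median shares of WT pre-B cells between 2.55% and 4.80% in the Ter5/wt;Rag1ko libraries, and 13 genes outside the list that were abundant in WT pre-B and near absent in Rag1ko cells implied between 0.404% and 1.33%, with a lowest ratio of 3.58. In Ter5H the shares were 15.1%, 7.56% and 34.7% against 1.99%, 1.77% and 12.3% (12 genes), with a lowest ratio of 2.83, in replicate 3. The genes outside the list included Polm and Fcrla, named above as higher in Ter5/wt;Rag1ko and in Ter5H cells. They also included Irs1, Col5a3 and Faim3, named as higher in Ter5H cells. A change of such genes within pro-B cells would raise their shares and lower the ratios. The quartile ranges of the list genes and of the genes outside the list overlapped in each of the 6 libraries, so a part from pre-B cells cannot be told apart from a change within pro-B cells. The profile of pre-B cells came from experiment 2. An effect of the alleles on pro-B cells stays open as well, and Sell was at 269 ± 37.4 CPM in Ter5/wt;Rag1ko cells, above both WT pre-B (136 ± 14.2 CPM) and Rag1ko cells (106 ± 22.4 CPM; SD, n = 3), a level that a mixture of these profiles does not give for this gene.

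Of the 21 Ighv1 genes tested, 14 were higher and 1 was lower in Ter5H∆TM than in Rag1ko pro-B cells, and the family was not tested as a list. A candidate explanation is that reads of the altered Igh allele were counted for related Ighv1 genes. If so, the 14 genes should be higher in Ter5/wt;Rag1ko cells, whose labels name a Rag1 knockout that would stop rearrangement, and the median log2 fold change there was 1.85 over 12 of the 14 genes (quartiles 1.01 and 3.17, 5 called). In Ter5H against Rag1ko cells the median of the 14 genes was 2.88, with 11 called higher. All Ighv genes together were at 38.3 ± 7.41 CPM in Ter5/wt;Rag1ko and 42.6 ± 3.79 CPM in the Rag1ko cells of experiment 2 (SD, n = 3). No biological explanation was tested, and rearranged V genes in the Ter5H∆TM mice, whose labels name no Rag1 knockout, stay open.

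The 6 libraries of each comparison can be divided into 3 against 3 in 10 ways, too few for a share under 0.05, and in each comparison 1 of the 10 gave as many genes as the real split, namely the real one. With the 2 groups alone, the real split gave 6565 genes for WT pre-B against Rag1ko and at most 0 for the others, 356 and 0 for Ter5/wt;Rag1ko against Rag1ko, 911 and 0 for Ter5H against Rag1ko, 58 and 52 for Ter5H∆TM against Rag1ko, and 528 and 7 for Ter5H∆TM against Ter5H. The split with 52 genes parted the libraries with low and high myeloid transcripts (Rag1ko replicate 1 and Ter5H∆TM replicates 1 and 2 against the other three), and with a myeloid covariate the real comparison gave 119 genes.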

How the results depend on the processing

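The myeloid covariate, the signature without interferon genes and both differences between experiments, with their alternatives, were chosen after seeing the data. Of the 570 values of named genes per comparison, called or not, 417 had no change of call under any alternative run. A call was lost in at least 1 alternative for 70 and gained in at least 1 for 83, and 0 reversed. Genes that were not called could not lose a call, so the 417 do not give the share of calls that held. Of the 43 list calls, 42 were lost with an estimated correlation, 3 with a replicate block, 2 with library totals and 1 with a myeloid covariate. The signature differences kept their direction in all 44 alternative values, but a p of 0.1 is the smallest their design allows, so their test says nothing about stability. With 50 genes per direction they were 2.41 for Ter5H and 0.45 for Ter5H∆TM against Rag1ko. Alternatives that needed experiments 1 or 4 were not run.

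Several counts of called genes moved by more than 1.5 times. A 2-fold threshold, by construction, left 3416 genes for WT pre-B against Rag1ko, 218 for Ter5/wt;Rag1ko, 602 for Ter5H and 304 for Ter5H∆TM against Ter5H. DESeq2 gave 549 genes for Ter5/wt;Rag1ko, 200 for Ter5H∆TM against Rag1ko, 1007 for Ter5H∆TM against Ter5H, and 82 and 295 for the differences of Ter5/wt;Rag1ko from Ter5H and from Ter5H∆TM. A replicate block gave 549 for Ter5/wt;Rag1ko and 184 for its difference from Ter5H∆TM, and no filter on low counts gave 701 for Ter5/wt;Rag1ko. The cause of these moves was not tested. A fit of the 2 groups alone, with fewer samples, gave 911 for Ter5H. For Ter5H∆TM against Rag1ko the count was 51 without the immunoglobulin genes, with fewer genes tested, and 119 with a myeloid covariate, for which the cause was not tested.

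Leaving out 1 library gave 6075 to 6831 genes for WT pre-B against Rag1ko, 156 to 302 for Ter5/wt;Rag1ko, 771 to 1306 for Ter5H, 45 to 98 for Ter5H∆TM against Rag1ko and 284 to 402 for Ter5H∆TM against Ter5H. For the differences between experiments it gave 5 to 47 and 57 to 150. With 3 libraries per group, real changes can be missed, since edgeR called between 70% and 90% of simulated 2-fold changes. Changes below 2-fold and changes of genes with few reads were not simulated, so the share missed among them is not known.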

Other observations

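The V gene and Ighv1-85 values were chosen after their values were seen. Kappa V gene transcripts, summed per library and scaled by library totals without TMM, were read at different levels in the groups. They were at 4.48 ± 1.003 CPM in Rag1ko pro-B cells of experiment 3 (SD, n = 3), 82.2 ± 44.8 CPM in Ter5H and 15.1 ± 2.14 CPM in Ter5H∆TM pro-B cells, with 11 to 13, 69 to 88 and 39 to 48 kappa V genes detected per library. In experiment 2 they were at 6.75 ± 0.123 CPM in Rag1ko, 10.8 ± 0.792 CPM in Ter5/wt;Rag1ko and 335 ± 70.4 CPM in WT pre-B cells. A single heavy chain V gene, Ighv1-85, took 21.9% to 29.4% of the Ighv counts in Ter5/wt;Rag1ko, 17.3% to 20.2% in Ter5H and 32.9% to 34.3% in Ter5H∆TM libraries, against at most 0.514% in the Rag1ko libraries and 1.20% to 1.34% in WT pre-B ones.

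Further lists differed between WT pre-B and Rag1ko pro-B cells, each with the same counts when adjusted over the list alone. In WT pre-B against Rag1ko pro-B cells, 14 of 18 genes of the MYC and ribosome biogenesis list were lower and 1 was higher, with Myc at -4.12 and the spermidine synthase gene Srm at -2.59 (adjusted p = 0.00261, and adjusted p = 0.231 with an estimated correlation). In Ter5/wt;Rag1ko against Rag1ko cells this list was called the other way, with 1 gene higher, Srm at 0.52 (2 adjusted over the list alone; median 0.24, adjusted p = 8.04e-06, and adjusted p = 0.266 with an estimated correlation), and the call of Srm was lost without any 1 of the 6 libraries (between 0.47 and 0.58). In Ter5H∆TM against Rag1ko cells edgeR called 0 of its genes (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, and 0 by DESeq2), with a median of -0.16 and the list called lower (adjusted p = 0.032, and adjusted p = 0.955 with an estimated correlation). In the glycolysis list 10 of 15 genes were lower (6 without WT pre-B replicate 1) and 2 higher in WT pre-B cells, such as Hk1 at -1.87 and Ldha at -1.18 (adjusted p = 0.0488, and adjusted p = 0.575 with an estimated correlation). In the NF-kB target list 12 of 15 were higher and 1 was lower there, with Cd40 at 4.52 and Nfkbia at 3.33 (adjusted p = 1.45e-05, and adjusted p = 0.231 with an estimated correlation). In the interferon response list 16 of 19 were lower and 2 higher in WT pre-B cells, with Ifit2 at -3.17 and Ifih1 at -2.81 (adjusted p = 0.00137, and adjusted p = 0.538 with an estimated correlation). The 7 tested markers of T and NK cells were all lower there, among them Thy1 at -5.76 and Lat at -5.79 (-6.55 without WT pre-B replicate 1) (adjusted p = 0.00261, and adjusted p = 0.231 with an estimated correlation). Of 10 markers of immature and mature B cells 8 were higher and 1 was lower in WT pre-B cells (adjusted p = 0.00164, and adjusted p = 0.136 with an estimated correlation). Of the 15 nonsense-mediated decay factors, 4 were higher and 1 lower in that comparison, with Upf1 at 0.48, and the list did not pass (adjusted p = 0.56). In Ter5/wt;Rag1ko against Rag1ko cells edgeR called 0 of these 15 factors, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. In Ter5H∆TM against Rag1ko cells the numbers were also 0, 0 and 0. In Ter5H against Rag1ko cells 1 of them was higher (0 adjusted over the list alone, 2 higher and 0 lower at an unadjusted p under 0.05, and 1 by DESeq2), Smg6 at 0.34, whose call was lost without any 1 library except Ter5H replicate 2 (between 0.26 and 0.37), and in Ter5H∆TM against Ter5H cells edgeR called 0, with 1 higher and 1 lower at an unadjusted p under 0.05 and 0 by DESeq2.

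Of the light chain constant genes, 2 were tested (Igkc and Iglc2), too few for a list test. Both were higher in WT pre-B and in Ter5H than in Rag1ko pro-B cells and lower in Ter5H∆TM than in Ter5H cells, also when adjusted over the list alone. The last call of Iglc2 was lost without any 1 of the Ter5H∆TM replicates 1, 2 and 3 (-2.83, -2.36 and -2.71) and in a fit of the 2 groups alone, and without Ter5H replicate 3 its log2 fold change was -1.64, and 3.59965 for Ter5H against Rag1ko cells. In Ter5/wt;Rag1ko against Rag1ko cells 1 was higher (2 adjusted over the list alone), and in Ter5H∆TM against Rag1ko cells edgeR called 0 (2 higher adjusted over the list alone, 2 at an unadjusted p under 0.05, and 2 by DESeq2).

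No difference was detected between the share of called genes near Rag1 and elsewhere in any of the 5 comparisons (Fisher's exact test, two-sided, adjusted p = 1 in each). Within 10 Mb on either side of it, 6 of 62 genes were called in Ter5H against Rag1ko cells, 9.68% against 10.9% of the genes elsewhere, and 3 of 62 in Ter5H∆TM against Ter5H cells, 4.84% against 4.54%.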
